A study of Rattus norvegicus with 6 samples.

How the data were processed

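RNA sequencing counts were analysed for 6 libraries of islets from fetal Sprague Dawley rats at gestational day 22. Per the labels and the series design, the fetuses of the left uterine horn received glucose at 4 mg/min for 48 h from gestational day 20, and the fetuses of the right horn of the same dam served as paired internal controls. Each library came from islets of 2 pooled pancreata, which were digested with collagenase, picked by hand and kept for 24 h in RPMI medium with 5 mM glucose before RNA was taken. Per the labels' protocols, libraries were made with a stranded poly(A) kit and run on a HiSeq instrument.

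The deposited values are raw counts of read pairs per gene, made by the authors with featureCounts 1.5.1 per the file headers. Per the file headers, the counting was set to paired reads on the reverse strand (strand setting 2), with a mapping quality of at least 10 and the UCSC refGene annotation of the rn6 genome. Per the submitters' processing notes, alignment used STAR 2.5, and edgeR 3.12.1 was named among the tools. Those notes name the mouse build mm10 beside rn6, whereas the file headers name only rn6. Counting by strand keeps antisense genes apart, but the quality minimum removes read pairs that map equally well to several places. Counts of genes with near-identical copies, such as defensins, globins, the RT1 (rat major histocompatibility) genes and the serine protease genes, are therefore uncertain. The files held 17321 genes, no row without a gene name, and no mitochondrially encoded gene.

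The group of each library was taken from its treatment label, and its pair from the stem of the sample title that a left-horn and a right-horn library share. In 6 of 6 libraries the horn letter in the deposited file name, and that of the alignment named in the file header, is the opposite of the letter in the sample title. The labels were used throughout, and groups are written as the libraries labelled high glucose and labelled control. If the file naming were right, the direction of each difference would be reversed and the p-values would stay as they are. Nothing in the counts settles this, since no gene was altered by design.

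Whether libraries of one dam vary together was checked from the deviations of log2 CPM from the group means. The correlation across genes was 0.474, 0.621 and 0.413 for libraries of the same dam, and between -0.454 and -0.004 for libraries of different dams. The deviations of a gene cancel out within each group, so positive values for the same dam force negative ones for different dams on balance. Genes are not independent replicates, so these values only describe the libraries. The pairing itself comes from the series design. No 2 libraries of a group matched within counting noise.

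Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, robust quasi-likelihood F-test, dam as a block plus treatment, Benjamini-Hochberg adjusted p below 0.05). The filter left 12276 genes, which hold 99.95% of the counts. Signs are labelled high glucose minus labelled control. CPM values use TMM-scaled library sizes. Gene lists were tested with camera in limma 3.58.1, two-sided, with its preset correlation of 0.01, on log2 CPM with a prior count of 2 and the same block. Adjustment was over the 32 lists with at least 5 tested members, out of 34 fixed. List calls were repeated with an estimated correlation and with fry, which tests whether the genes of a list move in one direction on balance. Symbols missing from the files were looked up among synonyms in a RefSeq table of the GRCr8 assembly, used for names only, which matched 11 list genes. Shares of counts were compared by a two-sided exact paired sign-flip permutation test, whose smallest p with 3 pairs is 0.25.

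The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names (a) 12 islet genes in any case, (b) among genes past the threshold with one direction in all 3 pairs, a mean count of at least 20 and a proper symbol, the 10 highest and 10 lowest log2 fold changes, (c) up to 3 passing genes per list, and (d) where fewer than 10 genes pass, the 10 smallest p-values that meet the other conditions of (b), as values that did not pass. Of the 12 islet genes, Mafa was not among the counted genes and is not analysed here. Some single-gene results are not reported here. List members given as examples were chosen after their values were seen. Another 3 lists (granulocyte, basal epithelial and spleen genes) were added after the gene results had been seen.

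Total counts per library lay between 18077841 and 30993532, and 13026 to 13976 genes had at least one count. The 10 most abundant genes took 5.36% to 9.02% of the counts. The procedure was tested on simulated counts for this comparison over 12146 genes. It recovered 42% of the 100 genes changed 2-fold (22% of the 50 with a mean count below 657, 62% of the others) and 85% of the 100 changed 4-fold, and 15 of its 150 calls were unchanged genes. Camera with the preset correlation found the shifted list and none of 30 unshifted lists, whereas with an estimated correlation it missed the shifted list. Fry gave the shifted list an unadjusted p of 0.0028. The simulation drew genes independently, so it did not test how camera behaves when genes vary together. Intervals on counts are 95% and were taken from counts summed over the libraries of a group. They cover counting error only and not the spread between libraries or dams. Since the reads carry no molecular identifiers, duplicate reads are counted too, and even the counting error may be larger than shown.

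Alternatives were a fit without the block, RLE and upper-quartile normalization, edgeR's likelihood ratio test, DESeq2 1.42.0, limma voom with and without sample weights, no filter on low counts, a minimum mean count of 50, other thresholds, leaving out marker genes of other cell types, and leaving out each pair in turn. Prior counts of 0.5 and 5, list tests without blood cell genes, and list tests with an estimated correlation and 1 pair left out were added later. No reference genome was used here, so GC content was not checked.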

Results

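Gene expression was measured by RNA sequencing in islets of fetal rats whose uterine horn had received a glucose infusion and in islets of fetuses from the opposite horn of the same dam. There were 3 libraries labelled high glucose and 3 labelled control, in 3 dam pairs, with 2 pooled pancreata per library. By the design, horn side went with treatment in all 3 pairs, so an effect of side cannot be told apart from one of glucose. An effect of the infusion procedure itself was not tested. Total counts were 30993532 and 30229658 in pair 1 (control, then high glucose), 18077841 and 22643755 in pair 2, and 29885104 and 29944494 in pair 3. The labels and the names of the deposited alignments disagree on the horn in all 6 libraries. Directions below follow the treatment labels and would be reversed under the other naming. Col3a1 and Col1a1, collagen genes of connective tissue, ranked among the 5 most abundant genes in each of the 6 libraries, and the insulin gene Ins1 in 5 of them. The Y-linked gene Eif2s3y had 2896 and 2869 counts in pair 1, 3 and 803 in pair 2, and 1840 and 14 in pair 3, so this marker of male fetuses moved in opposite directions in pairs 2 and 3. Ddx3y, a Y-linked gene with fewer counts, had 76 and 88, 14 and 16, and 58 and 39. Its raw counts moved in the same directions, but the rise in pair 2 was smaller than that of the total counts. Scaled for total counts it fell in pairs 2 and 3 and did not show that reversal.

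The first comparison asked which genes differ between islets of infused and control fetuses of the same dam. Of 12276 genes tested, 2 fell and none rose in the libraries labelled high glucose. Np4, a neutrophil defensin (rn6 chromosome 16, 75478554 to 75481111), had 23 to 1206 counts in the control libraries against 0 to 2. Summed over libraries this was 2 against 1352 counts, a ratio of 0.0014 (95% counting interval 0.00017 to 0.00508). Of the 1352 counts, 1206 came from the control library of pair 1. Without pair 1 the sums were 0 against 146 counts (upper 95% limit of the ratio 0.0221). Car1, carbonic anhydrase 1 of red cells (chromosome 2, 88185204 to 88227486), had 7 to 655 counts against 0 to 4, a ratio of the sums (5 against 874) of 0.00543 (0.00176 to 0.0127). The fitted log2 fold changes were -9.08 (SE 0.596, edgeR quasi-likelihood adjusted p = 0.000246) for Np4 and -7.32 (SE 0.581, adjusted p = 0.000793) for Car1. These fits depend on the prior count because the labelled high glucose libraries held so few reads. Np4 also belongs to a family of near-identical genes.

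The 10 genes that came next by p did not pass, and 9 of them were lower in the libraries labelled high glucose in all 3 pairs. Ifi27l2b, an interferon-inducible gene (chromosome 6, 127336305 to 127337791), measured 165 ± 94.2 CPM in control and 55.7 ± 21.4 CPM in high glucose (SD, n = 3), a log2 difference of -1.48 with an edgeR adjusted p of 0.0599. Irf7, the transcription factor that amplifies the interferon response (chromosome 1, 214249388 to 214252455), measured 117 ± 76.0 against 27.2 ± 16.1 CPM, a log2 difference of -1.95 with an edgeR adjusted p of 0.0699. Ccl21, a lymphoid tissue chemokine, had a log2 difference of -1.42 with an edgeR adjusted p of 0.109. The edgeR adjusted p was 0.143 for each of the others. Among these the log2 difference was -5.01 for Fcnb (a ficolin of myeloid cells), -2.87 for Cd52 (a leukocyte surface protein), -2.64 for Nfe2 (an erythroid and megakaryocyte transcription factor), -1.76 for the antiviral gene Oas1a, -1.48 for Fam46c and -1.31 for the RT1 gene RT1-S3. Krt17, a keratin of basal epithelia (chromosome 10, 88158993 to 88163712), was the exception, with 73.4 ± 44.8 CPM in control and 153 ± 71.0 CPM in high glucose.

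The number of genes called depended on the tool and on single pairs. DESeq2 called 106 genes (23 higher, 83 lower) and the edgeR fit without the block called 0, with 192 genes at an unadjusted p below 0.05. Leaving out pair 1, 2 or 3 gave 18, 18 and 55 genes. At an unadjusted p below 0.05 the blocked edgeR fit held 592 genes (205 higher, 387 lower), where chance alone gives 614.

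The genes that define the endocrine cells did not pass the test, and their differences changed sign between pairs. Ins1 (chromosome 1, 272799784 to 272800349) measured 8017 ± 3240 CPM in control and 5934 ± 3130 CPM in high glucose, with log2 differences of 0.77, -0.28 and -2.02 in pairs 1 to 3. Ins2 (chromosome 1, 215856967 to 215858034) measured 7105 ± 2680 and 5023 ± 3390 CPM, with log2 differences of 0.77, -0.41 and -2.46. The glucagon gene Gcg (0.36, 0.80 and -2.07) and the glucose transporter gene Slc2a2 (1.12, 0.92 and -2.60) also fell on both sides of 0. Slc2a2 passed when pair 3 was left out, with a log2 difference of 1.03 (edgeR adjusted p = 0.031). The fitted log2 differences were -0.73 for the somatostatin gene Sst (0.17, -1.22 and -1.14 in pairs 1 to 3, edgeR adjusted p = 0.952), -0.35 for Ppy, -0.25 for the transcription factor gene Pdx1, -0.03 for Nkx6-1, 0.40 for the endocrine progenitor factor Neurog3 and -0.23 for the glucose-induced gene Txnip. The edgeR adjusted p was 1 for each of these except Sst. Neurog3 had 0 to 87 counts per library and log2 differences of -0.83, 0.62 and 1.83 in pairs 1 to 3. Its mean was lower in high glucose (0.979 CPM) than in control (1.13 CPM), against the sign of the fit.

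**Figure D1:**
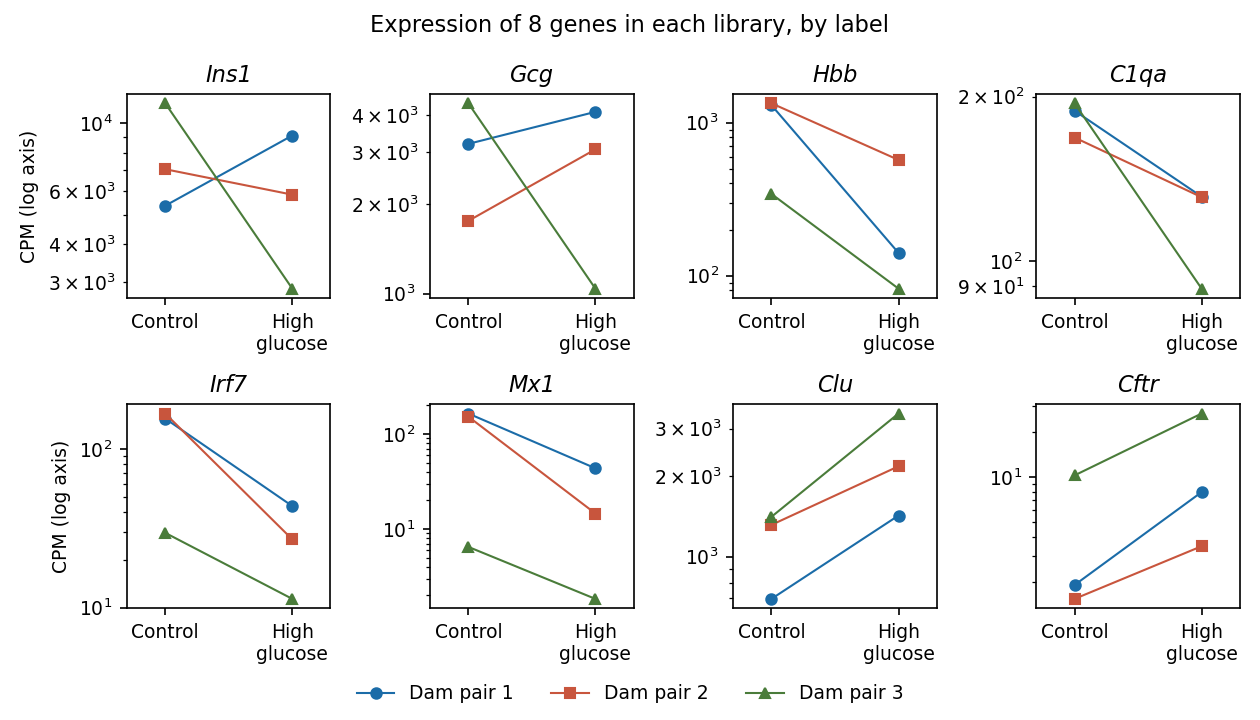
Expression of 8 genes in CPM (log axis) in each library, by treatment label, with a line for each of the 3 dam pairs. Hbb, C1qa, Irf7 and Mx1 are lower and Clu and Cftr higher in the library labelled high glucose of all 3 pairs, while Ins1 and Gcg move in different directions between pairs.

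The second comparison asked whether fixed groups of genes moved together. With the preset correlation, 12 of 32 lists passed (3 up, 9 down), and with an estimated correlation or with fry 0 passed, with smallest adjusted p-values of 0.77 and 0.57. No list held a gene called over all genes. With all 6 libraries the estimated correlation was 0.91 for beta cell, 0.82 for endothelial, 0.66 for erythroid and 0.56 for acinar genes. It was 0.08 for duct and 0.02 for cell cycle genes. Where genes vary together far more than the preset of 0.01 assumes, camera p-values with the preset are too small.

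Genes induced by interferon fell as a group in the libraries labelled high glucose. The median log2 difference of the 27 genes was -0.95 (camera adjusted p = 2.77e-24, and adjusted p = 0.77 with an estimated correlation). Of these genes 25 were lower in all 3 pairs, where chance gives 12.5% for a single gene. The genes vary together (estimated correlation 0.38), so this count is not evidence from 27 separate genes. Adjusted over the list alone, 19 genes passed, all lower. Gbp2, an interferon-induced GTPase, measured 170 ± 101 CPM in control and 73.3 ± 29.3 CPM in high glucose, and Mx1, which blocks viral replication, had a log2 difference of -2.39. Ifit2 and Bst2, antiviral effectors, had log2 differences of -1.22 and -1.01. The median was -1.26, -1.15 and -0.45 in pairs 1 to 3. DESeq2 called 14 of these genes, all lower.

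Blood cell genes moved in the same direction. The 9 erythroid genes had a median log2 difference of -3.22 (camera adjusted p = 5.15e-13, and adjusted p = 0.77 with an estimated correlation), and 4 passed when adjusted over the list alone. That median was -2.05 without pair 1 and -4.99 without pair 2. The beta-globin gene Hbb measured 994 ± 565 CPM in control and 264 ± 267 CPM in high glucose, and Alas2, which starts haem synthesis in red cell precursors, 42.1 ± 28.2 and 7.76 ± 10.7 CPM. Of 18 immune cell genes, 11 were lower in all 3 pairs and 11 passed when adjusted over the list alone. The median was -0.66 (camera adjusted p = 1.24e-08, and adjusted p = 0.77 with an estimated correlation), and -0.43 without pair 3. These included the macrophage complement genes C1qa (184 ± 13.7 against 117 ± 24.3 CPM), C1qb and C1qc, the leukocyte phosphatase Ptprc and the class II gene RT1-Db1. The 15 endothelial genes had a median of -0.45 (camera adjusted p = 2.56e-05, and adjusted p = 0.83 with an estimated correlation), with Cldn5, a tight junction gene, passing when adjusted over the list alone. That median was -0.68 without pair 1 and -0.13 without pair 2, and without pair 2 the list no longer passed (camera adjusted p = 0.48).

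Duct genes rose as a group. The 14 genes had a median log2 difference of 0.49 (camera adjusted p = 2.62e-05, and adjusted p = 0.77 with an estimated correlation), with medians of 0.70, 0.27 and 0.59 in the 3 pairs. Adjusted over the list alone, 2 passed, both higher. The chloride channel gene Cftr measured 4.58 ± 4.93 CPM in control and 12.7 ± 12.2 CPM in high glucose, and Clu (clusterin) 1139 ± 386 and 2337 ± 1010 CPM. Digestive enzyme genes of acinar cells had a median of 0.91 over 21 genes (camera adjusted p = 0.000316, and adjusted p = 0.83 with an estimated correlation), but 0 passed when adjusted over the list alone. Their medians were -0.55, 0.64 and 3.41 in the pairs, and the list's median was 1.96 without pair 1 and 0.07 without pair 3, where it did not pass (camera adjusted p = 0.50).

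The other 6 lists that passed had medians closer to 0. Cell cycle genes rose by a median of 0.17 over 39 genes (camera adjusted p = 0.00892), and none passed when adjusted over the list alone. Medians were lower for alpha cell genes (-0.43 over 10 genes, camera adjusted p = 0.00623), oxidative stress genes (-0.26 over 22, camera adjusted p = 0.00623) and oxidative phosphorylation (-0.17 over 50, camera adjusted p = 0.00337). They were also lower for endoplasmic reticulum stress (-0.16 over 27, camera adjusted p = 0.00892) and fatty acid oxidation (-0.15 over 23, camera adjusted p = 0.0273). With an estimated correlation the adjusted p was 0.77 for cell cycle and oxidative stress, 0.83 for alpha cell, reticulum stress and fatty acid genes, and 0.99 for oxidative phosphorylation. Adjusted over the list alone, 0 genes passed in the alpha cell, oxidative stress, oxidative phosphorylation and reticulum stress lists. Each of the 6 lists stopped passing when some single pair was left out. This held for oxidative stress and fatty acid oxidation without pair 1 (medians -0.16 and -0.16), for cell cycle and alpha cell without pair 2 (0.09 and -0.53), and for reticulum stress and fatty acid oxidation without pair 3 (-0.05 and -0.07). Without pair 3 the camera direction of the alpha cell and oxidative phosphorylation lists turned, at medians of -0.14 and -0.02.

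The beta cell list did not pass (21 genes, median -0.21, camera adjusted p = 0.115), and its median was 0.83, -0.12 and -1.58 in pairs 1 to 3. Single pairs turned its direction. Without pair 1 it was lower (median -0.84, camera adjusted p = 2.3e-08) and without pair 3 higher (0.31, camera adjusted p = 2.1e-05). With an estimated correlation neither passed (adjusted p = 0.76 without pair 1 and adjusted p = 0.92 without pair 3). With so few libraries left, that setting passed 0 lists, and the interferon list had the same values. Here and below it therefore cannot decide on a list. The camera p-values with the preset cannot decide on the beta cell list either. They assume a correlation of 0.01, while 0.91 was estimated for that list with all 6 libraries. The insulin secretion list (42 genes, median -0.05, camera adjusted p = 0.95) did likewise, at -0.37 (camera adjusted p = 0.0085) and 0.33 (camera adjusted p = 1.2e-06), again with adjusted p = 0.76 and adjusted p = 0.92 with an estimated correlation. Genes of the glucose-responsive factor ChREBP had a median of 0.01 and a mean of -0.12 over 17 genes (camera adjusted p = 0.678, direction down). For inflammation genes the median of 0.07 and mean of -0.03 also differed in sign. Without pair 1 the inflammation list passed at a median of 0.30 (camera adjusted p = 0.001), the mesenchyme list at -0.31 (camera adjusted p = 0.0028) and the delta, PP and epsilon cell list at -0.34 (camera adjusted p = 0.028), each with adjusted p = 0.76 with an estimated correlation. Without pair 3 cholesterol synthesis passed at 0.15 (camera adjusted p = 0.026) and immediate early genes at -0.14 (camera adjusted p = 0.013), both with adjusted p = 0.92 with an estimated correlation. The inflammation, mesenchyme and delta cell medians were -0.13, 0.14 and 0.20 without pair 3, so their sign also hung on single pairs. Across the 20 lists that did not pass, the camera adjusted p lay between 0.115 and 0.95.

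**Figure D2:**
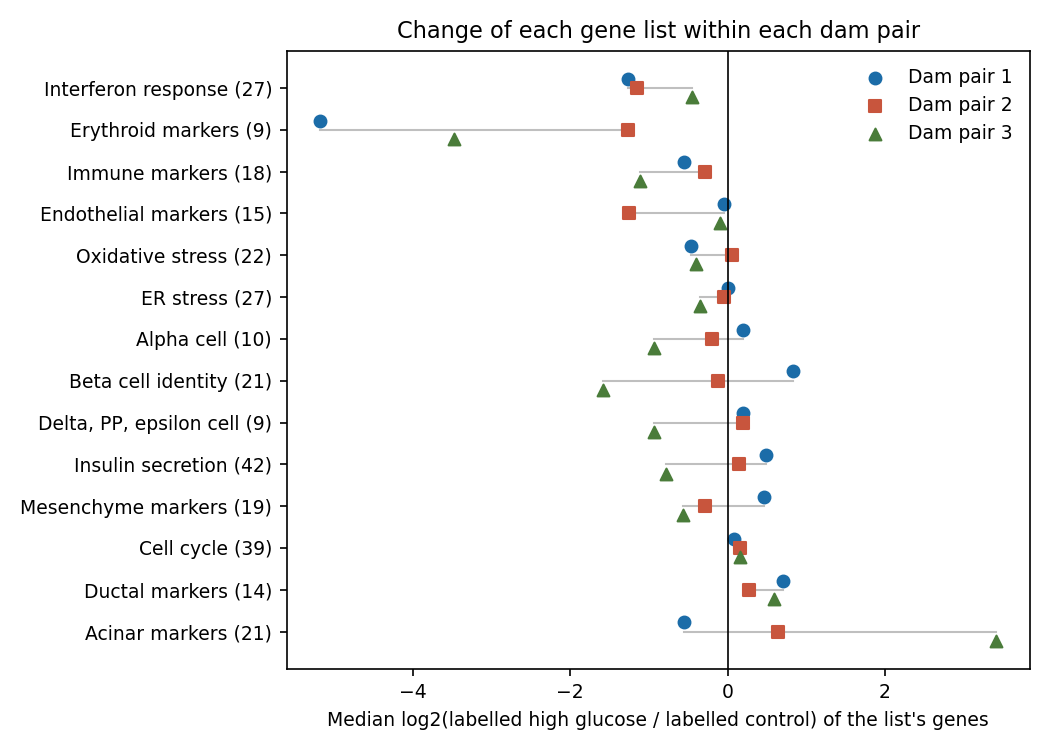
Median log2 ratio of labelled high glucose to labelled control over the genes of 14 fixed lists (number of tested genes in parentheses), with 1 point per dam pair, set apart vertically for legibility, and a line over their range. The interferon, erythroid and immune lists lie below 0 and the duct and cell cycle lists above 0 in all 3 pairs, while the beta cell list runs from -1.58 to 0.83 and the acinar list from -0.55 to 3.41.

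The third comparison took each list's share of all counts as a measure of tissue composition. Beta cell genes held 1.60% ± 0.59 of counts in control and 1.19% ± 0.76 in high glucose (SD, n = 3), and mesenchyme genes 4.33% ± 1.3 and 4.36% ± 0.60. Erythroid genes held 0.120% ± 0.072 and 0.0276% ± 0.026, immune genes 0.148% ± 0.039 and 0.103% ± 0.029, and duct genes 0.716% ± 0.14 and 1.02% ± 0.40. Of 36 shares 11 moved one way in all 3 pairs, where chance gives 25%, and the erythroid, immune, endothelial and duct shares were among them. The 11 also include the granulocyte and basal epithelial lists, put together after gene results from these libraries had been seen, so the count is no evidence beyond chance. Each of the 11 had an exact sign-flip p of 0.25, the smallest the design allows, so no share could pass (Benjamini-Hochberg adjusted p of at least 0.82 over 36 shares, each tested two-sided). The mean difference in the beta cell share was -0.408 percentage points with all pairs, -0.982 without pair 1 and 0.255 without pair 3. For mesenchyme it was 0.0282 with all pairs and -0.409, 0.194 and 0.299 without pairs 1, 2 and 3. It moved from 0.303 to 0.153 for duct genes without pair 3, from -0.0924 to -0.0561 for erythroid genes without pair 1, and from -0.0311 to -0.00554 for endothelial genes without pair 2. The shares are set by a few abundant genes in each list and do not count cells.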

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

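The tests of prior counts, of lists without blood cell genes and of an estimated correlation with 1 pair left out were chosen after the data were seen. Np4 and Car1, the 2 genes called, were among the calls of every alternative except the fit with no replicate block, which called 0 genes (their log2 fold changes were then -8.93 and -7.17, adjusted p = 1). The number of calls was 4 with upper-quartile normalization, with voom, with voom sample weights and at an adjusted p below 0.10, 5 at a mean count of at least 50, 18 with no filter, 72 with the likelihood ratio test and 106 with DESeq2. It ranged from 18 to 55 when 1 pair was left out. RLE factors and leaving out acinar, erythroid and sex-linked genes gave 2. Neither Np4 nor Car1 is a member of those lists, so leaving the lists out could not remove these calls. The list count of 12 was 0 with an estimated correlation and 0 with fry, 10 with no filter, 12 with no replicate block, and 12 with RLE factors and with other prior counts. Without blood cell genes it was 10, since the erythroid and immune lists were then not tested, and every other passing list still passed. It was 9 to 15 without 1 pair. With an estimated correlation and without any 1 pair it was 0, a setting with few libraries in which even the interferon list did not pass. The fit with no replicate block changed no list call. The interferon, erythroid, immune and duct lists passed with each pair left out. Without pair 3 the camera direction of the alpha cell and oxidative phosphorylation lists turned, although their medians stayed below 0 (-0.66 to -0.14 and -0.30 to -0.02 without 1 pair). Without pair 3 the beta cell list (-0.84 to 0.31), the insulin secretion list (-0.37 to 0.33) and Slc2a2 (-0.88 to 1.03) turned and passed. The cause was not tested. For the 12 lists that passed, 94 of 166 values under alternatives kept the camera direction and the call, 68 kept only the direction and 4 turned, with 0 medians changing sign. For the 20 others, 271 of 280 did not pass, 7 passed in the direction first found and 2 in the opposite one. Both tallies are in part fixed by the settings. Those with an estimated correlation or fry passed 0 lists, so no call could be kept there, and like the other prior counts they reuse the medians of another fit. Shares without mitochondrially encoded genes could not be computed, since no such gene was counted. In simulated counts 22% of 2-fold changes were recovered below a mean count of 657 and 62% from there on, and sequencing depth itself was not varied.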

Other observations

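The medians of 2 further gene lists, put together after single genes had been seen, kept their sign in the 3 pairs, although 6 of the 10 granulocyte genes were lower and 4 of the 12 basal epithelial genes higher in all 3. The granulocyte list (median log2 difference -2.56) contains Np4 and Fcnb, which prompted it, along with Camp (cathelicidin, -3.19) and Mmp9 (-0.67). The basal epithelial list (median 0.52) contains Krt17, Wnt7a (1.14) and Gabrp (1.57). Camera adjusted p-values were 2.31e-12 and 1.17e-05, and with an estimated correlation 0.51 for both. Neither is independent evidence, since the genes were chosen from these libraries. Among other single genes, chosen after their values were seen, Tlx1, a transcription factor needed to form the spleen, measured 14.8 ± 1.93 CPM in control and 5.34 ± 1.32 CPM in high glucose (log2 difference -1.49, edgeR adjusted p = 0.160), and Ctgf, a matrix-associated growth factor, was higher in all 3 pairs (log2 difference 0.88, edgeR adjusted p = 0.277).

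Of the tests below, those on splits of the libraries and on spleen genes were set before their results were seen, and the others after. The 6 libraries can be split in 10 ways into 3 and 3. Counting the real split itself, in 5 of 10 splits the blocked fit called at least as many genes as the real split (2, highest other 14). In 5 of 10 it called at least as many lists (12, highest other 13). With 10 splits a share below 0.05 cannot be reached. All the other splits with as many genes part 1 pair only. In the blocked fit such a split measures the difference between labels in that pair, and each of these contrasts occurs in 2 splits with the same values. These counts over splits therefore cannot tell chance from treatment. The other 3 splits that part all 3 pairs called 0 genes but 11 to 13 lists, so the number of lists passing with the preset correlation does not set the treatment apart. The smallest camera p of any list was 8.67e-26 in the real split, for the interferon list, and 1.78e-14, 2.54e-08 and 3.19e-12 in those 3. Only the interferon list had a p below the smallest of each of those 3. The erythroid list (3.22e-14) had a larger p than the smallest of 1 of them, the immune list (1.16e-09) than that of 2, and the endothelial (3.20e-06) and duct (4.09e-06) lists than that of all 3. This ranking does not single out the interferon list, which was named because its p was the smallest in the real split. Those 3 splits are few, and each reverses 1 pair and keeps 2, so they are not free of treatment. The interferon list's own camera p in them was 1.56e-10, 0.614 and 0.0524.

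The first pattern is the lower interferon response in the libraries labelled high glucose. The values argue against the sex makeup of the pooled fetuses as the sole cause. Counts of the Y-linked gene Eif2s3y moved in opposite directions in pairs 2 and 3 while the interferon median was -1.15 and -0.45. In pair 1 they were 2896 and 2869 while that median was -1.26. A contribution of sex beside another cause is not excluded. The argument from pairs 2 and 3 rests on 1 gene, as Ddx3y (14 and 16 counts in pair 2, 58 and 39 in pair 3) did not show the reversal once scaled for total counts. Fewer immune cells may account for part of it and stays open. The interferon median minus the immune median was -0.71 and -0.87 in pairs 1 and 2 but 0.66 in pair 3, so a smaller number of immune cells and lower expression per cell cannot be told apart here. The interferon list's share of counts was 0.377%, 0.4% and 0.211% in the controls of pairs 1 to 3. It was 0.235%, 0.18% and 0.16% in high glucose. Mx1 measured 164, 152 and 6.48 CPM in those controls and 43.5, 14.55 and 1.84 CPM in high glucose. Pair 3 thus had the lowest control level, below that of high glucose in pair 1. Raised expression in the controls of pairs 1 and 2 and lowered expression in high glucose cannot be told apart. An effect of the infusion, or of the horn side that went with it, was not tested apart from these explanations and stays open.

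The second pattern is the lower erythroid signal. Fewer blood cells left in the libraries labelled high glucose and lower expression per cell cannot be told apart, because the values at hand (0 erythroid genes above 1 CPM in control were higher in any pair) only restate the pattern. By the counts of Eif2s3y alone, the values also argue against the sex makeup of the pooled fetuses as the sole cause, with medians of -1.26 and -3.47 in pairs 2 and 3. Spleen tissue left in the control libraries, prompted by Tlx1 and Ccl21, was tested with 10 other spleen genes (median -0.94), of which Tcf21, Lyve1 and Stab2 are also expressed in other tissues. Their median was -1.30 and -0.95 in pairs 1 and 3 but -0.07 in pair 2, 3 of the 10 were lower in all 3 pairs, and their share of counts was higher in high glucose in pair 3, so this stays open, as does an effect of the treatment on blood cell number.

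The third pattern is the disagreement between pairs in beta cell genes, 0.83, -0.12 and -1.58. A different share of endocrine cells in each library could produce it, and then alpha, delta and beta genes should move together within a pair. They had the same sign in 2 of the 3 pairs, in pair 1 (0.83, 0.20 and 0.20) and pair 3 (-1.58, -0.94 and -0.94), but not in pair 2 (-0.12, -0.20 and 0.20), where the log2 differences of Ins1, Gcg and Sst were -0.28, 0.80 and -1.22 and the alpha share of counts rose while the beta share fell. A common change in these cells was thus not seen in pair 2, and their share and a change in expression per cell cannot be told apart with 3 pairs. No biological explanation for the difference between dams was tested.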
